A study of Mus musculus with 24 samples.

How the data were processed

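Quadriceps muscle of C57BL/6JN mice was profiled by stranded poly-A RNA-seq in 24 libraries, 3 for each combination of 2 ages, 2 sexes and 2 treatments. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2 and kallisto were used with the mouse genome build mm10; their order, versions, annotation release and filters are not given in the sources used here. The authors deposited 1 matrix of transcript abundances in TPM, and each of the 24 columns sums to 1000000. It holds 105129 transcripts under 33641 gene symbols. TPM keeps no read totals, so depth and counting error are unknown, and a share taken up by a few genes lowers all others in the same library. Transcripts of 13 mitochondrial genes took 21.7 to 30.8% of TPM. Pseudogenes are not counted in this share. Reads were not used here.

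Of the transcripts, 103723 (98.66%) matched GENCODE M21 when version numbers were ignored, and 99593 with them. Identifiers and mm10 coordinates of genes come from that release; 94 symbols covered more than 1 gene identifier and 207 had no gene in it. Transcript TPM was summed by symbol. Genes with at least 1 TPM in at least 3 libraries were tested (13005 genes), as log2(TPM + 1). Limma 3.58.1 in R 4.3.3 fitted a mean for each of the 8 groups over 24 libraries with an intensity trend in the empirical Bayes step (16 residual degrees of freedom, prior 3.42). Sexes or ages were averaged with equal weight. P values were adjusted by Benjamini-Hochberg over all tested genes within each comparison, with a threshold of 0.05, and all adjusted p values are two-sided and from limma unless another test is named. Python 3.11.15 was used for the remaining computations.

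Samples were grouped by the labels for age, sex and treatment. Replicate numbers follow the order of the samples, and library 3 of each group is the one whose title carries a number from 17 to 24. No number pairs an animal with another. The comparisons, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Per comparison the rule took 10 anchor genes, the 8 largest rises and 8 largest falls past 0.05 with the same sign in both sexes, and up to 4 members of each list past 0.05 by smallest p. Where fewer than 10 genes passed, it took the 5 smallest p values. For sex, it took the sex-linked check genes (Xist, Ddx3y, Kdm5d, Uty and Eif2s3y) and the 5 largest rises and falls. Predicted genes were counted but not described. Genes named within old males, Adipoq, Amd1 and Smox were picked after their values were seen.

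The 30 gene lists were tested for 5 comparisons with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. After seeing the data the same tests were run for 7 more: treatment within each age and sex, age within each sex, and the sex difference in old mice. Camera called 11 lists in old males, 19 in old females, 9 in young males, 6 in young females, 14 and 17 for age in males and females, and 14 for the sex difference. With an estimated correlation 1 was called in old males, 1 for the sex difference and 0 in the other 5. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. Benjamini-Hochberg adjustment ran over the lists of a comparison. The treatment and age effects were correlated across genes, beside data simulated with no effects (20 runs) and with the old vehicle libraries split between the comparisons.

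The position of library 3 was measured in each group over genes with a mean of at least 10 TPM. It was fitted as a mix of libraries 1 and 2, with a weight of library 1 between 0.35 and 0.86. The pair from its own group gave the best mix in 8 of 8 groups. Because of this, every comparison was also fitted on the 16 libraries with title numbers 1 to 16 (8 residual degrees of freedom, prior 3.63), an alternative chosen after seeing the data. Both fits were tested on simulated data in which 200 of 13005 genes changed. With 3 independent libraries per group, 203 genes were called, 16 of them false, and 82% of changes of 0.5 log2 units were found. With a mixed library 3 and 24 libraries fitted, 1030 were called, 836 of them false. With the same data and 16 libraries fitted, 173 were called, 11 of them false, and 46% of changes of 0.5, 97% of changes of 1 and 100% of changes of 2 log2 units were found. If library 3 is a mix, p values from 24 libraries are too small. The noise added to the simulated mix was no larger than the smallest spread of any gene. The measured library 3 may lie further from an exact mix, so the number of false calls in the data may be smaller than in the simulation.

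Alternatives changed the scaling between libraries (TMM-like factors written for this work in place of those of a package, and quantile normalization), the filter (none, or a mean of at least 5 TPM), the pseudocount (0.1 and 5), the empirical Bayes step (robust, no trend), library weights, the samples fitted, the model (a covariate for title numbers 17 to 24, an additive sex term), the feature (single isoforms) and the replicates (each left out in turn). Added after seeing the data were the fit of 16 libraries, the same with TMM-like scaling, fits of the same size with libraries 1 and 3 or 2 and 3 of each group, the removal of 413 mitochondrial, erythroid and immunoglobulin genes with the rest rescaled, and 10 further comparisons, among them the sex difference of the treatment effect in old mice and the age effect within each sex. Splits of the samples were refitted as described with the results of that test.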

Results

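Gene expression was measured by poly-A RNA-seq in quadriceps muscle of C57BL/6JN mice, in 24 libraries that fall into 8 groups of 3. The groups combine age, sex and treatment, with 12 libraries per age. Old mice were 24 months old at the start of treatment and young mice were 4 months old. Prednisone, a synthetic glucocorticoid used as an anti-inflammatory drug, was injected intraperitoneally once a week at 1 mg/kg at lights-on, and controls received vehicle. Muscles were taken 4 hours after the last injection. The number of weekly injections is not given in the sources used here. Values are TPM (transcript abundances scaled to a fixed sum), which keep no read totals, so the depth of each library is unknown. Between 11495 and 12270 genes reached 1 TPM in a library.

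In each group, library 3 lay between libraries 1 and 2 more often than chance order gives. Among genes with a mean of at least 10 TPM that spanned at least 2-fold within a group, library 3 held the middle value in 55.2 to 91.3% of genes, against 33.3% for exchangeable libraries. Libraries 1 and 2 held the middle value in at most 26%. These were 41 to 209 genes per group. Over all genes with a mean of at least 10 TPM, library 3 held the middle value in 46 to 64.1%. Library 3 was the most frequent middle library in 8 of 8 groups (exact binomial test, one-sided p = 0.000152). Fitted as a weighted mix of libraries 1 and 2 of its group, it differed from the mix by a robust SD of 0.084 to 0.1 log2 units. Libraries 1 and 2, compared directly without a fit, differed by 0.164 to 0.341. Each fitted as a mix of the other 2, library 1 differed by 0.104 to 0.237 and library 2 by 0.104 to 0.266. Library 3 was the closest to its mix in 8 of 8 groups, narrowly in young male vehicle (0.097 against 0.104 for library 2). Data were then simulated with no effects and a library 3 made as a mix of libraries 1 and 2. For treatment in old mice, a limma fit of 24 libraries called a median of 730 genes there. A fit of libraries 1 and 2 alone called 0. The noise added to the simulated mix was no larger than the smallest spread of any gene, so 730 may overstate the false calls in the data. Gene counts and many named genes therefore carry a second value from the 16 libraries numbered 1 and 2. A log2 difference or adjusted p given once comes from 24 libraries unless 16 are named. The terms rose and fell are kept for genes past an adjusted p of 0.05 in both fits, and group levels are means over libraries 1 and 2.

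**Figure D1:**
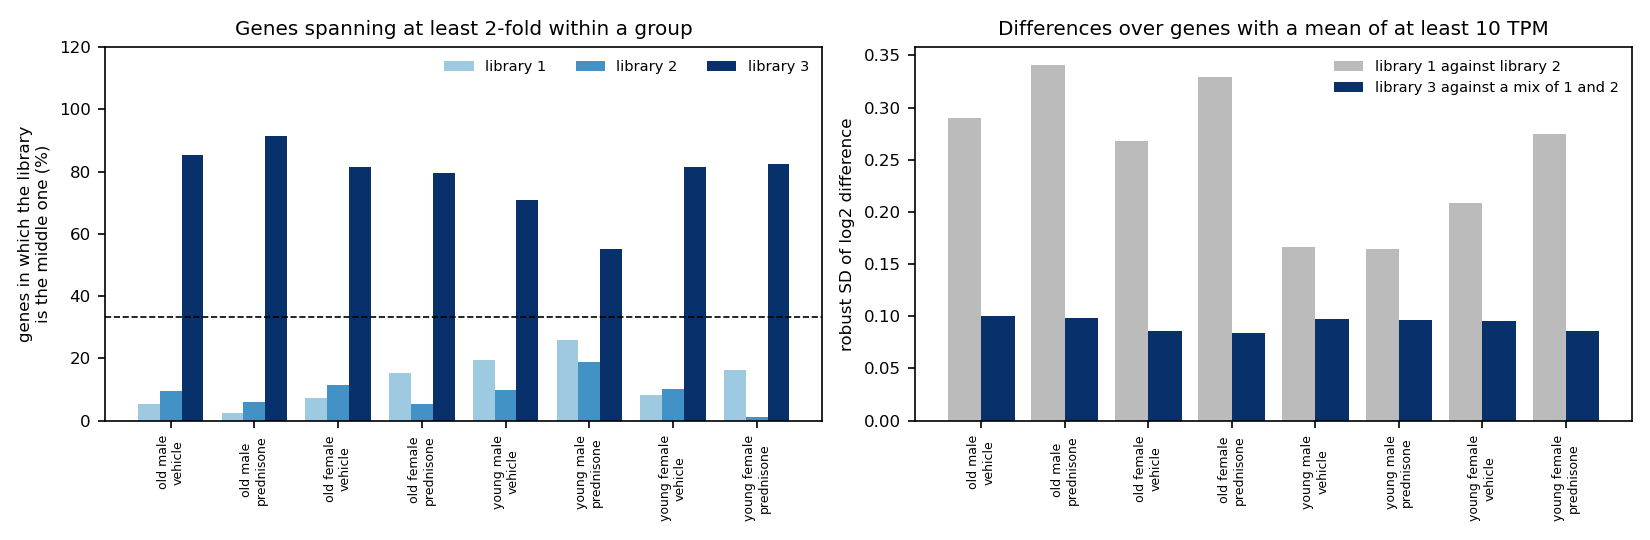
Left, the percent of genes (mean of at least 10 TPM, at least a 2-fold range within the group) in which each library holds the middle value, with a dashed line at 33.3%; right, the robust SD of log2 differences between libraries 1 and 2 (grey) and between library 3 and a fitted mix of them (blue). Library 3 is the tallest bar in all 8 groups, and its difference from the mix is at most 0.1.

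The first comparison asked how weekly prednisone changed muscle expression in mice that were old at the start, with the sexes averaged. Ky, which encodes a muscle protein needed for muscle growth and sarcomere upkeep (ENSMUSG00000035606.8, chromosome 9, 102505750 to 102546239, plus strand; mm10 coordinates of GENCODE M21 here and for other genes), rose by 1.21 ± 0.11 (log2, SE; adjusted p = 3.09e-06 with 24 libraries and 0.0382 with 16). Its level was 13.6 ± 2.66 TPM in old male vehicle muscle (mean ± SD, n = 2) and 60.8 ± 15.7 with prednisone. In old females Ky stood at 35.3 ± 7.6 and 44.6 ± 9.96 TPM and did not pass (adjusted p = 0.296). The immunoglobulin variable segments Igkv3-5, Igkv9-120 and Ighv2-9-1 fell as well. Each B cell clone uses a single heavy and a single light chain segment of this kind. Ighv2-9-1 was at 13.6 ± 3.53 TPM in old male vehicle muscle, listed at 0 in old males with prednisone, and at a mean of at most 0.103 TPM in the other 6 groups. Igkv3-5 was at 25.3 ± 22.5 and 0.121 ± 0.171 TPM in old males and at 3.8 ± 2.84 and 0.686 ± 0.97 in old females, where it did not pass (adjusted p = 0.182). Igkv9-120 did not pass in old females either (0.158). Ighv2-9-1 and Igkv9-120 lie outside the rule for named genes and were named after their values were seen. The predicted genes Gm17402 and A930018M24Rik also rose, which completes the 6 genes past 0.05 in both fits.

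More glucocorticoid-induced genes were lower than higher with prednisone in old mice in the fit of 24 libraries. Of 26 measured members, 2 were higher and 16 lower past 0.05, and 2 and 20 when adjusted over the list alone. With 16 libraries 0 passed, and 10 were lower when adjusted over the list alone. The list was called by camera (adjusted p = 6.83e-10) and kept its call with an estimated correlation (adjusted p = 0.0405), but not with an estimated correlation on 16 libraries (adjusted p = 0.201). Fkbp5, a co-chaperone of the glucocorticoid receptor and one of its standard target genes (ENSMUSG00000024222.17, chromosome 17, 28399094 to 28517527, minus strand), differed by -1.17 ± 0.12 (adjusted p = 6.91e-06 and 0.0555). Cdkn1a, which encodes the cell cycle inhibitor p21, differed by -1.05 ± 0.15 (adjusted p = 0.000344 and 0.195). This mean describes neither sex: Cdkn1a fell in old males and did not pass in old females, where its estimate was positive. The effects of the sexes differed by 2.74 (log2, female minus male). Rasd1, a small GTPase induced by dexamethasone, went the other way at 1.05 ± 0.28 (adjusted p = 0.0249 and 0.434).

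The muscle atrophy program had 7 of 18 members lower and 0 higher with 24 libraries, 7 and 1 when adjusted over the list alone, and 0 past 0.05 with 16. Its camera adjusted p was 0.00244, and 0.39 with an estimated correlation. Trim63, the ubiquitin ligase MuRF1 (ENSMUSG00000028834.13, chromosome 4, 134315120 to 134329629, plus strand), differed by -1.01 ± 0.12 (adjusted p = 6.91e-05 and 0.141). The second atrophy ligase, Fbxo32, differed by -0.77 ± 0.16 (adjusted p = 0.00855 and 0.39). Of the PGC1alpha and Lipin1 axis, 0 of 14 members passed in either fit. Ppargc1a, the coactivator of mitochondrial biogenesis, differed by 0.60 ± 0.24 (adjusted p = 0.131 and 0.647), and Lpin1, a phosphatidate phosphatase and coactivator, by -0.17 ± 0.11 (adjusted p = 0.347 and 0.723). Nuclear-coded oxidative phosphorylation genes had 0 of 40 members past 0.05. Their median was -0.05 while camera's direction was up (adjusted p = 0.802). Pdk4, the kinase that inhibits pyruvate dehydrogenase, differed by -1.38 ± 0.23 (adjusted p = 0.00149 and 0.268).

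In 5 lists of markers of other cell types and of matrix, members past 0.05 with 24 libraries were lower. Macrophage and myeloid markers had 10 of 17 members lower, endothelial markers 7 of 12, smooth muscle and pericyte markers 6 of 9, Schwann cell markers 4 of 10, and extracellular matrix genes 3 of 22. Adjusted over the list alone, these counts were 14, 9, 7, 9 and 3. With 16 libraries 0 members of these lists passed. All 5 lists were called by camera and none with an estimated correlation (adjusted p = 0.388, 0.388, 0.278, 0.39 and 0.519, in the same order). Of the circadian clock genes, 4 of 18 were higher and 1 lower with 24 libraries (8 and 1 adjusted over the list alone), and 0 passed with 16. The list was called upward, with an adjusted p of 0.178 under an estimated correlation. The clock activator Arntl (Bmal1) differed by -0.66 ± 0.08 (adjusted p = 6.91e-05 and 0.0643), and the clock repressors Bhlhe41 and Bhlhe40 by 0.67 ± 0.1 and 0.54 ± 0.08. Camera called 15 of the 30 lists in all, 8 up and 7 down, and fry called 1 up and 9 down. Other splits of the samples, described below, called a median of 10 lists by camera. TCA cycle, glycolysis, branched-chain amino acid, adiponectin and AMPK, adipocyte, erythroid and immediate early genes completed the upward calls, with estimated-correlation adjusted p from 0.388 to 0.519.

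In the limma fit of 24 libraries, 1126 of 13005 genes passed 0.05 for treatment in old mice, 294 higher and 832 lower. With TMM-like scaling the split was 844 higher and 662 lower. With 16 libraries 6 genes passed, 3 higher and 3 lower (7 and 5 with TMM-like scaling), and 1334 had an unadjusted p under 0.05, where 650 would be expected by chance. The count with 24 libraries ran from 607 without old male prednisone replicate 1 to 1850 without old male prednisone replicate 2.

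Treatment was then tested within each age and sex. In old males 99 genes passed in both fits, 9 higher and 90 lower, relative to a median over all genes of -0.134 with 24 libraries and -0.153 with 16. With TMM-like scaling of the 16 libraries 83 passed, 33 higher and 50 lower. The genes below were named after their values were seen. Fkbp5 fell (log2 -1.69 ± 0.16; adjusted p = 2.26e-06 and 0.0209), from 69.4 ± 14.2 TPM with vehicle to 19.9 ± 3.76 with prednisone (n = 2). The metallothioneins Mt2 and Mt1, metal-binding stress proteins, fell (-2.66 and -2.16). Mt2 went from 628 ± 76.4 to 97.2 ± 36.4 TPM. Cdkn1a fell (-2.42), from 110 ± 39.2 to 19.9 ± 10.1 TPM. Trim63 fell (-1.57), from 814 ± 204 to 268 ± 90.8 TPM, and Pdk4 fell (-2.49), from 641 ± 42.7 to 113 ± 25.6 TPM. Arntl fell (-1.33), while Dbp, a clock output factor, rose by 1.32 (adjusted p = 0.00684 and 0.0311 with 16 libraries). The adhesion molecule Vcam1, the macrophage mannose receptor Mrc1, the chemokine Cxcl13 and the iron-binding protein Lcn2 fell (-1.17, -1.08, -2.28 and -2.25, in this order).

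By list, 21 of 26 glucocorticoid-induced genes were lower in old males with 24 libraries and 8 with 16 (22 and 19 adjusted over the list alone). The estimated correlation gave an adjusted p of 0.0243 with 24 libraries and 0.111 with 16. Clock genes had 11 of 18 members higher and 3 lower, and 2 and 1 with 16 libraries (adjusted p = 0.0542 with an estimated correlation). Erythroid markers had 6 of 6 higher and 0 past 0.05 with 16 libraries (adjusted p = 0.271 with an estimated correlation). Old male prednisone replicate 1 held 14.22% of its TPM in erythroid markers, replicate 2 held 0.75% and replicate 3 held 6.25%, against 0.39 to 0.55% in the vehicle libraries. In the fit of 24 libraries 3175 genes passed, 583 higher and 2592 lower, but 1698 higher and 1348 lower with TMM-like scaling. Without old male prednisone replicate 1 the count was 1522.

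**Figure D2:**
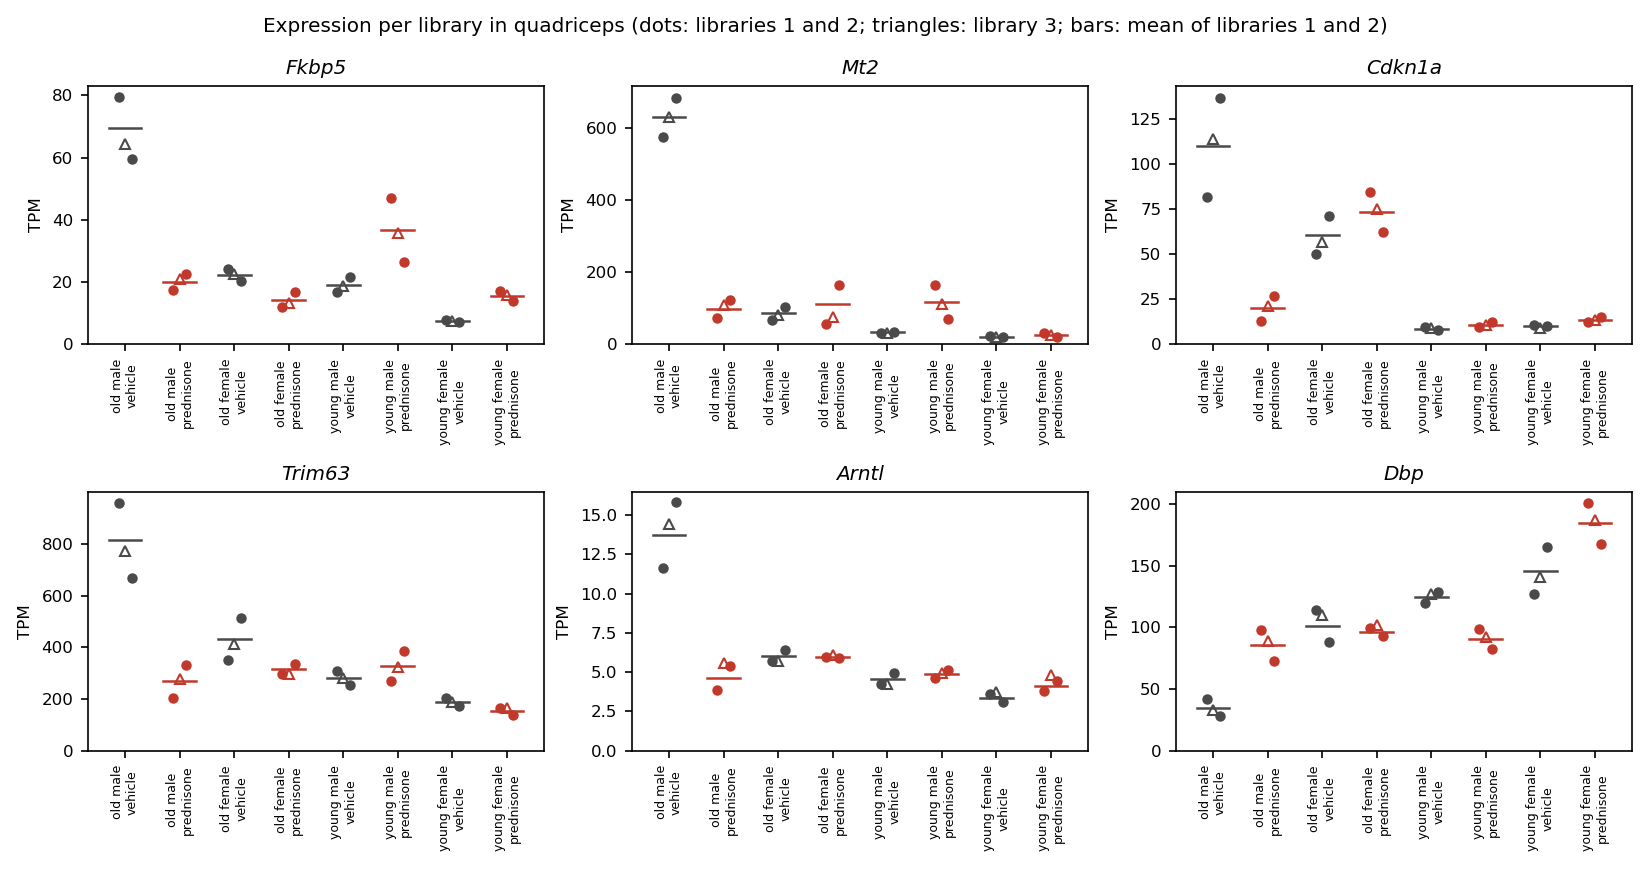
TPM of Fkbp5, Mt2, Cdkn1a, Trim63, Arntl and Dbp in each library of the 8 groups (dark grey, vehicle; red, prednisone; dots, libraries 1 and 2; triangles, library 3; bars, mean of libraries 1 and 2). For Fkbp5 the old male vehicle libraries sit at 59.4 to 79.4 TPM, above every library of the other 7 groups.

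**Figure D3:**
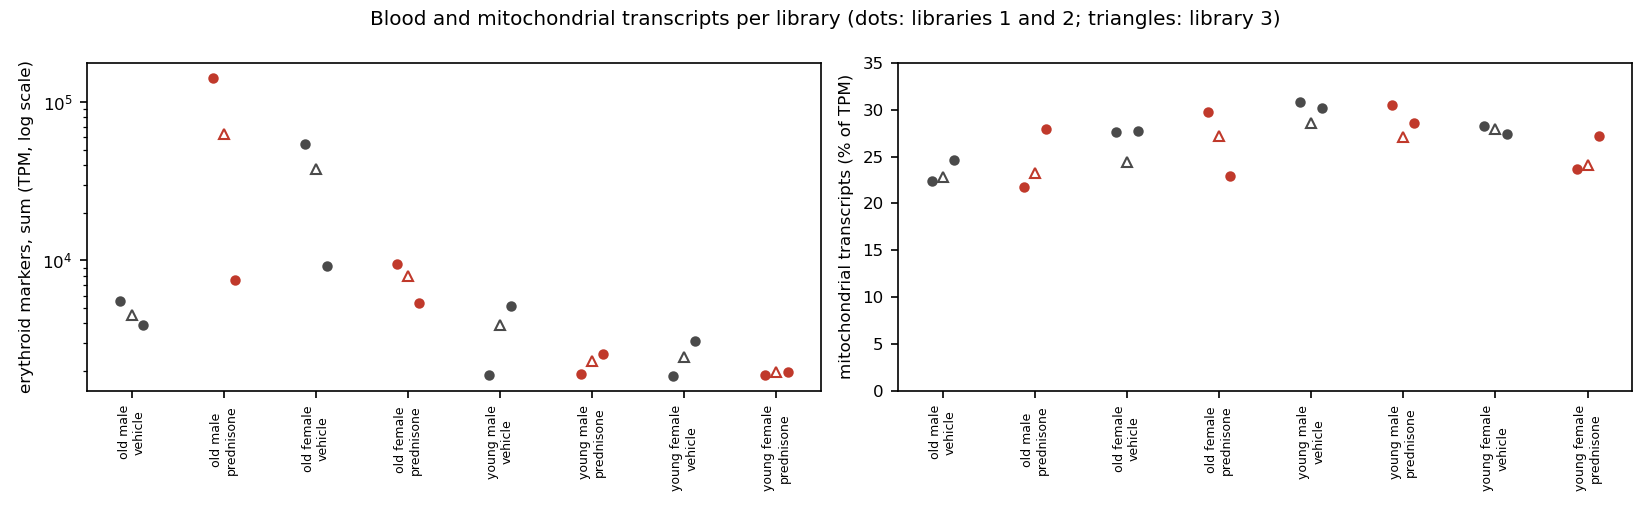
Left, summed TPM of 6 erythroid markers on a log axis; right, mitochondrial transcripts in percent of TPM, for each library of the 8 groups (dots, libraries 1 and 2; triangles, library 3). Erythroid TPM is highest in old male prednisone replicate 1, and mitochondrial shares run from 21.7 to 30.8%.

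In old females 122 genes passed with 24 libraries, 108 higher and 14 lower. With 16 libraries 1 gene passed, the predicted gene Gm17402, and 512 had an unadjusted p under 0.05. The count ran from 20 without old female vehicle replicate 1 to 423 without old female vehicle replicate 2. Fkbp5 differed by -0.66 ± 0.16 (adjusted p = 0.0659), Cdkn1a by 0.32 ± 0.21 (0.606) and Trim63 by -0.45 ± 0.17 (0.271). The sex difference of the treatment effect in old mice, tested after the strata were seen, is given with the sex comparisons.

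In mice that were young at the start, the same question drew a smaller response with 24 libraries. Fkbp5 was higher by 0.92 ± 0.12 (adjusted p = 0.0011), in males (19.1 ± 3.6 to 36.8 ± 14.6 TPM, n = 2) and in females (7.43 ± 0.283 to 15.4 ± 2.27 TPM). With 16 libraries its adjusted p was 0.758. Car14, a carbonic anhydrase (ENSMUSG00000038526.14, chromosome 3, 95897768 to 95904691, minus strand), differed by 0.66 ± 0.08 (adjusted p = 0.0011 and 0.3). Mstn, the growth factor myostatin that limits muscle mass (ENSMUSG00000026100.6, chromosome 1, 53061640 to 53068079, plus strand), differed by 0.61 ± 0.11 (adjusted p = 0.0312 and 1.0). The lymphatic and macrophage receptor Lyve1 differed by 0.80 ± 0.15, the integrin Itgam by 0.50 ± 0.09, the thioesterase Acot2 by 0.51 ± 0.09 and the synaptic kinase Musk by 0.42 ± 0.08. Ppargc1a (0.30 ± 0.24, adjusted p = 0.649), Lpin1 (0.41 ± 0.11, 0.104) and Trim63 (-0.03 ± 0.12, 0.941) did not pass in either fit.

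Camera called 9 lists in young mice and none with an estimated correlation. Macrophage and myeloid markers had 1 of 17 members higher (14 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation). Adipocyte markers had 0 of 11 past 0.05 and 8 lower when adjusted over the list alone, and interferon response genes 0 of 17 and 6 lower (adjusted p = 0.275 for each with an estimated correlation). Glycolysis genes had 0 of 17 past 0.05 and 5 higher when adjusted over the list alone (0.275). Glucocorticoid-induced genes had 1 of 26 higher, and 6 higher and 2 lower when adjusted over the list alone, with a camera adjusted p of 0.872. In all, 18 genes passed with 24 libraries, 14 higher and 4 lower, and 39 higher and 43 lower with TMM-like scaling. The count ran from 2 without young male prednisone replicate 3 to 98 without young female prednisone replicate 2. With 16 libraries the predicted gene Gm3788 alone passed, which did not pass with 24, and 473 genes had an unadjusted p under 0.05. Within the sexes, 24 genes passed in young males and 25 in young females with 24 libraries, the latter 18 higher and 7 lower, and 6 higher and 11 lower with TMM-like scaling. With 16 libraries these counts were 0 (380 at an unadjusted p under 0.05, limma) and 1 (495). The count in young males ran from 2 without young male vehicle replicate 1 to 46 without old male prednisone replicate 1. That in young females ran from 0 without young female vehicle replicate 2 to 763 without young female prednisone replicate 2.

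The age by treatment interaction tested whether the response to prednisone differed between old and young mice. Fkbp5 passed in both fits: its treatment effect was lower in old than in young mice by -2.10 ± 0.16 (adjusted p = 9.29e-07 and 0.0322). The second gene past 0.05 in both was Ighv2-9-1, present above 1 TPM in old male vehicle libraries alone. In the fit of 24 libraries Mt2 differed by -2.27 ± 0.31, Lcn2 by -1.85 ± 0.21, Cdkn1a by -1.40 ± 0.21, Trim63 by -0.98 ± 0.17, Foxo1, a transcription factor of the atrophy program, by -0.87 ± 0.18 and Arntl by -0.84 ± 0.11. The adipocyte receptor gene Adrb3 differed by 1.97 ± 0.47 and the desaturase Scd1 by 1.78 ± 0.47. None of these 8 passed with 16 libraries, where their adjusted p ran from 0.0514 to 0.573. For Cdkn1a the effect in old mice averages a fall in old males with a positive estimate in old females. Lpin1 differed by -0.57 ± 0.15 (adjusted p = 0.0327 and 0.59), and Ppargc1a (0.29 ± 0.34, adjusted p = 0.666) passed in neither fit.

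By list, macrophage and myeloid markers had 12 of 17 members lower in the interaction (16 adjusted over the list alone), glucocorticoid-induced genes 10 of 26 (13 lower and 2 higher adjusted over the list alone), smooth muscle and pericyte markers 5 of 9, and extracellular matrix genes 4 of 22. Adipocyte markers had 5 of 11 higher and 8 adjusted over the list alone. With 16 libraries only 1 member of these lists, Fkbp5, passed. Camera called 16 lists, 8 up and 8 down, and none with an estimated correlation (adjusted p from 0.211 to 0.45). Fry called 1 up and 11 down. In all, 749 genes passed with 24 libraries, 156 higher and 593 lower, and 387 higher and 387 lower with TMM-like scaling. With 16 libraries 2 passed, both lower (3 higher and 3 lower with TMM-like scaling), and 1064 had an unadjusted p under 0.05. The count ran from 457 without young male vehicle replicate 1 to 1269 without old male prednisone replicate 2.

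The treatment effect was also averaged over ages and sexes, which does not test whether the groups share it. Only Ighv2-9-1 passed in both fits, through old male vehicle muscle alone. With 24 libraries, Mstn was higher by 0.44 ± 0.08 (adjusted p = 0.0061 and 0.649), Irs1, the insulin receptor substrate, by 0.47 ± 0.11 (0.0462 and 0.889), and the clock repressors Bhlhe41 and Bhlhe40 by 0.45 ± 0.07 and 0.36 ± 0.06. Trim63 differed by -0.52 ± 0.09 (0.00443 and 0.649), Pdk4 by -0.91 ± 0.16 (0.0081 and 0.649) and the arrestin Arrdc2, a glucocorticoid-induced gene, by -0.67 ± 0.15 (0.0337 and 0.857). Fkbp5 (-0.13 ± 0.08, 0.455) did not pass. Glucocorticoid-induced genes had 5 of 26 members lower with 24 libraries and 0 with 16 (14 and 1 adjusted over the list alone), with an adjusted p of 0.126 under an estimated correlation. Clock genes had 4 of 18 higher and 1 lower, and 0 with 16 libraries (0.281). Camera called 10 lists, 4 up and 6 down, and none with an estimated correlation. In all, 179 genes passed, 79 higher and 100 lower, and 288 higher and 168 lower with TMM-like scaling. With 16 libraries 1 passed, and 704 had an unadjusted p under 0.05. The count ran from 62 without old female vehicle replicate 3 to 556 without old male vehicle replicate 1.

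The age effect in vehicle mice gave the background on which treatment acted, and it held the most genes past 0.05 in both fits among the comparisons that average the sexes: 438, of which 330 rose and 108 fell. Among them were 7 of 18 genes of denervation and the neuromuscular junction. Musk, the kinase that organises the synapse (ENSMUSG00000057280.15, chromosome 4, 58285960 to 58374303, plus strand), rose by 1.13 ± 0.08 (adjusted p = 1.13e-08 and 0.000866), from 8.0 ± 1.34 to 14.5 ± 1.01 TPM in males and from 3.23 ± 0.16 to 11 ± 0.767 TPM in females (n = 2). Chrna1, an acetylcholine receptor subunit, rose by 1.5 ± 0.13, the transcription factor Runx1 by 1.64 ± 0.13 and the stress gene Gadd45a by 2.51 ± 0.2. Of all members 12 were higher and 1 lower with 24 libraries, and 7 higher with 16 (13 and 1, and 11 and 1, adjusted over the list alone). The list's adjusted p was 0.157 with an estimated correlation and 0.00287 by fry on 16 libraries, which tests whether the genes move on balance in 1 direction.

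Cdkn1a rose with age by 2.99 ± 0.15 (adjusted p = 1.01e-10 and 0.000135; ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727, plus strand) and Eda2r, a p53-induced receptor, by 1.80 ± 0.12. Among senescence and p53 targets, 6 of 12 members were higher and 2 lower, and 2 higher with 16 libraries (6 and 1 adjusted over the list alone). The list's adjusted p was 0.331 with an estimated correlation and 0.00287 by fry on 16 libraries. Glucocorticoid-induced genes had 14 of 26 members higher and 1 lower, and 5 higher with 16 (17 and 2, and 6 and 0, adjusted over the list alone; adjusted p = 0.157 with an estimated correlation, and 0.00287 by fry on 16 libraries). Fkbp5 rose by 1.62 ± 0.12, Mt2 by 3.11 ± 0.22 and Mt1 by 2.07 ± 0.17. With 16 libraries these 3 passed within males (adjusted p = 0.00757, 0.00282 and 0.00313) and not within females (0.0679, 0.195 and 0.361). In the atrophy program 12 of 18 members were higher and 1 lower, and 4 higher with 16 libraries (12 and 1, and 9 and 0, adjusted over the list alone; 0.331 with an estimated correlation). Trim63 rose by 1.33 ± 0.12 and Foxo1 by 1.10 ± 0.13. Old male vehicle muscle stood highest for these 2: Trim63 was at 814 ± 204 TPM there, 431 ± 114 in old female vehicle muscle, and 280 ± 40.6 and 188 ± 21.8 in young males and females.

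Few members of the immune lists passed in both fits, more with 24 libraries alone. Macrophage and myeloid markers had 16 of 17 members higher with 24 libraries and 2 with 16 (17 and 15 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation and 0.045 by fry on 16 libraries), among them the protease Ctss at 1.17 ± 0.14. Lymphocyte and immunoglobulin markers had 9 of 13 higher and 2 with 16 (0.351 with an estimated correlation). The kappa constant region Igkc rose by 3.54 ± 0.36 and the joining chain Jchain by 2.29 ± 0.28. Interferon response genes had 9 of 17 higher and 2 with 16, Oas2 and Zbp1 (0.351). The chemokines Ccl8 and Cxcl10 rose by 3.27 ± 0.33 and 1.56 ± 0.23. Erythroid markers were higher in 6 of 6 and passed in 0 with 16 libraries (0.356). Old female vehicle replicate 1 held 5.41% of its TPM in them.

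Of 4 metabolic lists, some members were lower with age in the fit of 24 libraries. Nuclear-coded oxidative phosphorylation genes had 19 of 40 members lower and 0 higher, TCA cycle genes 6 of 15, branched-chain amino acid genes 8 of 17, and glycolysis genes 7 of 17 with 1 higher. With 16 libraries 0 members of these 4 lists passed, and their adjusted p with an estimated correlation was 0.356, 0.351, 0.356 and 0.356. Uqcrc1, a complex III subunit, differed by -0.29 ± 0.05 (adjusted p = 0.000591 and 0.0987). Extracellular matrix genes had 11 of 22 lower and 2 higher, and with 16 libraries only Timp1, a protease inhibitor, passed, which rose by 1.10 ± 0.14 (0.5 with an estimated correlation). Of the clock genes, 9 of 18 were lower and 2 higher, and 4 lower and 1 higher with 16 libraries (0.351). Arntl rose by 1.03 ± 0.08, while Dbp, Per3 and Nr1d2 fell (-1.17, -0.6 and -0.47). Within the sexes, Arntl, Dbp and Nr1d2 passed in males with 16 libraries (0.00313, 0.00313 and 0.00359) and not in females (0.166, 0.465 and 0.679). Ky fell (-1.43 ± 0.11; adjusted p = 2.27e-08 and 0.0015). The tendon factor Scx rose by 1.10 ± 0.1. Ppargc1a (0.54 ± 0.24, adjusted p = 0.116) did not pass in either fit.

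**Figure D4:**
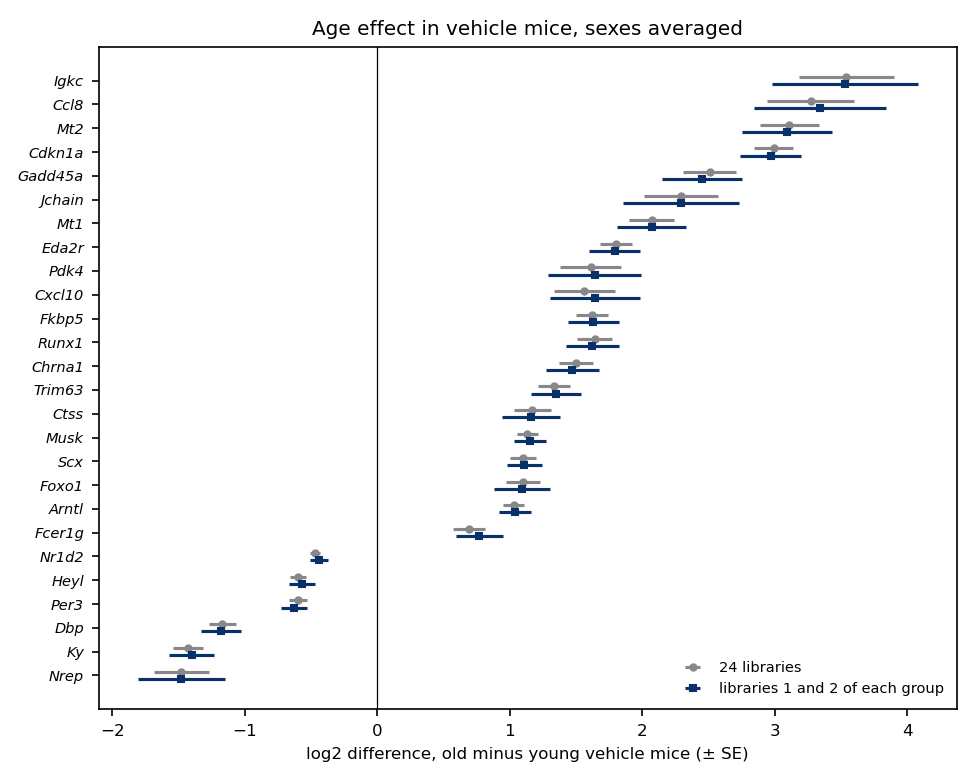
Log2 difference between old and young vehicle mice (sexes averaged, ± SE) of 26 genes past an adjusted p of 0.05 in both fits, from 24 libraries (grey circles) and from libraries 1 and 2 of each group (blue squares). Estimates of both fits lie close together, and the bars are wider with 16 libraries. The 16 libraries are part of the 24, so this closeness is no independent check.

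With 24 libraries 3231 genes passed for age, 1949 higher and 1282 lower, and 1744 higher and 2159 lower after quantile normalization. With TMM-like scaling of the 16 libraries 708 passed, 443 higher and 265 lower. With 16 libraries unscaled, 2537 had an unadjusted p under 0.05. Camera called 17 lists, 9 up and 8 down, and fry 12 up and 7 down. Heat shock (5 of 10 higher), adipocyte (3 of 11 lower) and smooth muscle genes (4 of 9 lower) completed camera's calls, each at an adjusted p of 0.356 with an estimated correlation. Split by sex after the data were seen, the age effect gave 163 genes in males and 12 in females with 16 libraries, 160 and 12 of them shared with the fit of 24. With 24 libraries 1079 genes passed within females and 2493 within males. The age effect averages the sexes and so rests in part on the old male vehicle libraries. Their group mean was outside the range of the 6 groups other than old males in 90 of the 99 genes past 0.05 for treatment in old males. These 99 genes were chosen by a difference of that group, so they do not tell how much of the age effect depends on it. If that group differs for a reason other than age, or its label was exchanged, the age values change with it.

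Whether prednisone moved genes against the direction of age was asked across 13005 genes, which are not independent replicates. Treatment effects in old mice and age effects correlated at r = -0.51 (Spearman's rho -0.46), but both use the old vehicle libraries, and data simulated with no effects gave r = -0.49. The covariance was -0.038 against a simulated -0.01 with 24 libraries, and -0.041 against a simulated -0.02 with 16. With the old vehicle libraries split between the 2 comparisons, r ran from -0.42 to -0.17 over 18 splits of the 24 libraries. If a library of each group is a mix of the others, these 18 splits do not remove the sharing, because the mix and its sources fall on both sides. With 16 libraries r was -0.50 observed and -0.50 simulated, and -0.22 to -0.08 over 4 splits. With no library shared, treatment in old males against age in females gave r = -0.10 (rho -0.15), and treatment in old females against age in males gave r = 0.11 (rho -0.03), so the sign of the latter depends on the coefficient. Of genes past 0.05 with 24 libraries, 486 were lower with prednisone and higher with age, where 124.7 would be shared by independent lists, and 9 were lower in both (82 by independence). The shared vehicle libraries favour opposite directions in these counts.

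Sex was compared among vehicle mice, as female minus male, which also checks the labels. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were lower in females (-4.43, -4.78, -2.73 and -1.87). No value of the X-linked check gene Xist is given here, so the check rests on Y-linked genes. Ddx3y was at 28.3 ± 3.11 and 23.2 ± 2.17 TPM in old and young male vehicle muscle and at 0.266 ± 0.0472 and 0.136 ± 0.0706 TPM in females (n = 2). Myh7, the slow myosin heavy chain (ENSMUSG00000053093.16, chromosome 14, 54970684 to 54994626, minus strand), was higher in females by 4.08 ± 0.56 (adjusted p = 6.37e-05 and 0.0442), at 145 ± 143 and 66.2 ± 27.6 TPM in old and young females against 4.28 ± 5.95 and 6.01 ± 0.314 in males. Mup18, a major urinary protein, was higher by 3.77 ± 0.53, and Ddit4, an inhibitor of mTORC1, was lower (-2.69 ± 0.26; adjusted p = 1.11e-06 and 0.0104). With 24 libraries 1314 genes passed, 762 higher and 552 lower in females, and 616 higher and 830 lower with TMM-like scaling. With 16 libraries 136 passed, 62 higher and 74 lower, 135 of them shared, and with TMM-like scaling 61 higher and 123 lower.

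The sex by treatment interaction tested whether females and males responded differently, with the ages averaged. The immunoglobulin segment Ighv2-9-1 alone passed in both fits, again through old male vehicle muscle. With 24 libraries 559 genes passed, 543 with a higher effect in females and 16 with a lower one, relative to a median over all genes of 0.138. With TMM-like scaling 95 passed, 65 higher and 30 lower. The count ran from 200 without young female prednisone replicate 1 to 1537 without young female prednisone replicate 2. In old mice alone, 1825 genes differed between the sexes, 1610 higher and 215 lower, relative to a median of 0.168, and 749 and 846 with TMM-like scaling. Of 26 glucocorticoid-induced genes, 16 had a higher effect in females and 0 passed with 16 libraries (adjusted p = 0.0303 with an estimated correlation, and 0.135 on 16 libraries). With 16 libraries Ighv2-9-1 was the 1 gene past 0.05, and 1816 had an unadjusted p under 0.05. The count ran from 1037 without old female vehicle replicate 1 to 2417 without old male prednisone replicate 2.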

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

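The tests of abundant genes, of the old male vehicle group and of clock phase, and the fits of 16 libraries, were chosen after the result was seen; those of blood and of exchanged labels were written down before their values were known.

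Differences between groups, each tested as an interaction, singled out 9 results. The response to prednisone differed between ages at 749 genes, between sexes at 559 and between old females and old males at 1825, with 24 libraries. With libraries 1 and 2 of each group these counts were 2, 1 and 1. Fits of the same size with library 3 gave 1601, 1999 and 2438 genes (libraries 1 and 3) and 244, 36 and 626 (libraries 2 and 3), so the drop does not come from the number of libraries alone. Between ages, old minus young, the treatment effects differed by -2.1 for Fkbp5, -2.27 for Mt2 and -0.98 for Trim63 (log2; adjusted p = 0.0322, 0.249 and 0.413 with 16 libraries). Between sexes of old mice, female minus male, they differed by 1.03 for Fkbp5, 2.74 for Cdkn1a and -1.66 for Ky (adjusted p = 0.00767, 3.7e-05 and 0.000161 with 24 libraries, and 0.271, 0.133 and 0.133 with 16).

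More genes were lower than higher with prednisone in old males (81.6% of 3175). After removal of mitochondrial, erythroid and immunoglobulin genes and rescaling, 49.2% of the genes past 0.05 were lower. The median over all genes went from -0.134 to -0.015. Scalings that remove no gene gave 44.3% (TMM-like) and 40.4% (quantile). They centre all genes whatever the source, so they do not bear on it. The removed genes held 23.7 to 25.2% of TPM in old male vehicle libraries and 28.8 to 36% in old male prednisone libraries. The excess of lower genes thus goes with the larger share of these abundant genes. TPM cannot tell a rise of these genes from a fall of all others, and what changed the share was not tested. Blood in 1 prednisone library is not settled as the source. Fold changes from disjoint library pairs correlated at 0.13 or more. Without old male prednisone replicate 1, 247 genes were higher and 1275 lower, but replicate 3 still held 6.25% of its TPM in erythroid markers. The old male vehicle group stood apart as well, with 90 of the 99 genes past 0.05 in both fits outside the range of the other 6 group means in that group, and 32 in the prednisone group. A difference of the old male vehicle mice from all others therefore stays open beside an effect of the drug.

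Of 26 glucocorticoid-induced genes, 21 were lower with prednisone in old males with 24 libraries and 8 with 16, while Fkbp5 was higher in young mice with 24. Exchanged labels of the 2 old male groups could give this. Treatment effects of old and young males correlated at r = -0.08 and rho = -0.18, where an exchange predicts r under -0.2. Those of old males and young females correlated the other way, at r = 0.16 and rho = 0.22. Pairs without old males ran from r = -0.14 to 0.17. The prediction needs a treatment effect shared by the groups, which these pairs do not show, so an exchange is not settled. Another clock phase in the old male vehicle mice cannot be told apart from this either. It needs evening clock genes lower and Arntl, Clock and Nfil3 higher in old male vehicle than in old male prednisone muscle: 8 of 8 evening genes were lower in both pairings, and Arntl (0.82 to 1.64) and Nfil3 (0.16 to 1.18) were higher, but Clock was not (-0.04 to 0.25). Age and sex, which the design names, stay open as biological explanations.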

How the results depend on the processing

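The fits of title numbers 1 to 16 and of library 3 with 1 other library, the former with TMM-like scaling or an estimated correlation, the removal of abundant genes, the sex difference in old mice and the comparisons without shared libraries were chosen after seeing the data. TPM keeps no read totals, so no limit from depth could be set. No paired analysis was possible because no number links 2 samples. Where 1 group is left with 2 libraries, the pooled spread of all groups was used. Unless a reason is given, the cause was not tested.

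With TMM-like scaling, 82 genes passed for treatment in young mice, 456 for treatment over all mice, 95 for sex by treatment and 61 for treatment in young males; with quantile normalization 88, 414, 103 and 67; with no filter 7, 84, 285 and 8. With a mean of at least 5 TPM, which tests fewer genes, 822 passed for sex, and 70, 14 and 88 for treatment in old females, young males and young females. With a pseudocount of 5, 47 passed in young females. With a covariate for title numbers 17 to 24, 11 passed in young mice, 79 in old females and 16 in young females. With abundant genes removed, 69 passed for sex by treatment, 16 in young females and 1138 for the sex difference in old mice.

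Array weights gave library 3 of each group more weight (1.54 to 38.7, against 0.18 to 1.1 for the others). They gave 8870 genes for treatment in old mice, 3797 in young mice, 6594 for age by treatment, 6262 over all mice, 7874 for age, 7418 for sex by treatment, 6340 for sex, 10477 in old males, 6345 in old females, 1244 in young males, 6844 in young females and 9085 for the sex difference in old mice. These weights favour the library that lies between the other 2 of its group.

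With only the groups in the comparison fitted, which uses fewer samples, 232 passed in old mice, 118 in young mice, 350 in old males, 0 in old females, 0 in young females and 709 for the sex difference in old mice. With an additive sex term, 174 passed in old mice, 0 in young mice, 89 for age by treatment and 4 over all mice. With single isoforms, 581 passed in old mice, 1 in young mice, 252 for age by treatment, 62 over all mice, 108 for sex by treatment, 24 in old females, 2 in young males, 0 in young females and 927 for the sex difference in old mice.

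With title numbers 1 to 16, which drops library 3 of each group, 6 passed in old mice, 1 in young mice, 2 for age by treatment, 1 over all mice, 438 for age, 1 for sex by treatment, 136 for sex, 99 in old males, 1 in old females, 0 in young males, 1 in young females and 1 for the sex difference in old mice. With TMM-like scaling added these were 12, 1, 6, 1, 708, 1, 184, 83, 1, 0, 1 and 1, in the same order. With libraries 1 and 3 of each group, 157 passed in young mice, 1601 for age by treatment, 1999 for sex by treatment, 502 in old females, 63 in young males and 501 in young females. With libraries 2 and 3, 613 passed in old mice, 10 in young mice, 244 for age by treatment, 36 for sex by treatment, 1545 in old males, 25 in old females, 14 in young males and 626 for the sex difference in old mice.

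With an estimated correlation, 1 list was called for treatment in old mice and 0 in the other 4 comparisons, and with 16 libraries 0 in all 5. With fry, 2 lists were called in young mice (both up) and 3 over all mice (2 up, 1 down). The correlation of treatment and age effects was -0.29 (median of 18) with the old vehicle libraries split and -0.16 (median of 4) with 16 libraries, -0.67 over age genes, -0.10 for old males against age in females and 0.11 for old females against age in males, where Pearson's r reversed but Spearman's rho (-0.03) did not.

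With 1 replicate left out, counts ran from 607 to 1850 in old mice, 2 to 98 in young mice, 457 to 1269 for age by treatment, 62 to 556 over all mice, 2668 to 3506 for age, 200 to 1537 for sex by treatment, 988 to 1470 for sex, 1522 to 3757 in old males, 20 to 423 in old females, 2 to 46 in young males, 0 to 763 in young females and 1037 to 2417 for the sex difference in old mice. Lists ran from 14 to 17, 7 to 12, 14 to 18, 8 to 13 and 16 to 20 (old, young, interaction, all, age), and the correlation from -0.54 to -0.46.

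Of 417 values of named genes, 401 kept their side of the threshold with TMM-like scaling, 397 with quantile normalization, 404 and 406 with pseudocounts of 0.1 and 5, 405 with a robust empirical Bayes step, 409 with no trend, 397 with the covariate, 377 with array weights, 346 with no filter and 360 with only the groups in the comparison. With libraries 1 and 3 of each group 372 kept it, with libraries 2 and 3 318, with title numbers 1 to 16 144 and with TMM-like scaling added 148. With an additive sex term 181 of 337 kept it, with a mean of at least 5 TPM 329 of 332, with abundant genes removed 361 of 382 and with 1 replicate left out 9135 of 10008. None reversed under these settings.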

Other observations

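The tests of mixing by gene class and of the order of the 3 libraries, and those of other splits of the samples, were chosen after the results were seen; the 2 tests on genes seen in 1 library and the splits of 16 libraries for lists were written down before, though the minimum number of genes the former need was set after.

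Fat and fibre type markers varied within old females, and the genes here were chosen after their values were seen. Adipoq, the adipocyte hormone adiponectin, was at 53.4 and 147 TPM in vehicle libraries 1 and 2 and at 248 and 253 TPM with prednisone. Adipocyte markers had 5 of 11 members higher with 24 libraries and 11 when adjusted over the list alone, and 0 passed with 16 (adjusted p = 0.119 with an estimated correlation). Slow fibre genes had 0 of 9 past 0.05, and 9 lower when adjusted over the list alone (0.119). Myh7 was at 246 and 44.5 TPM in vehicle libraries 1 and 2. Erythroid markers had 0 of 6 past 0.05, and 6 lower when adjusted over the list alone (0.181).

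Amd1 and Smox, enzymes of polyamine synthesis and breakdown, stood higher in young male than in young female vehicle muscle, and were likewise chosen after their values were seen. Amd1 was at 543 ± 41.8 TPM in young male and 100 ± 10 in young female vehicle muscle (mean ± SD, n = 2). Of the old male vehicle libraries, replicate 1 was at 440 TPM and replicate 2 at 98.5. Smox was at 272 ± 34.6 and 82 ± 6.32 TPM in young males and females, and at 255 and 95.1 TPM in old male vehicle libraries 1 and 2.

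Among genes with at least a 2-fold range within a group, the third library was most often the middle one in 8 of 8 groups, more than chance order gives. A candidate explanation is that it holds RNA or reads of the other 2. Weights fitted on gene classes lay within 0.15 of that of the group in 11 of 13. The group weight was fitted on all genes, these classes included, so abundant classes pull it toward their own weight. The 11 of 13 is therefore not an independent check. In the 3 groups with at least 2 classes, the 8 class weights lay closer within groups than after exchange between groups (exact permutation p = 0.0095, 420 arrangements). This shows that the weights differ by group. It cannot exclude an independent library with a smaller spread, since 1 that resembles library 1 or 2 in several classes would also give close weights. The other 5 groups have 1 class each, 3 of them within 0.15 of the group weight, too few to tell there. Genes seen in 1 library were too few, and went both ways: 13 genes in 6 group sides, with a median share of 0.29 in library 3. The 1 side with at least 3 genes was near its weight, with 6 immunoglobulin segments at shares of 0.31 to 0.47, but 4 sides had a median share of 0, with 6 genes not found in library 3. Pooled RNA and pooled reads were not told apart, and no biological explanation was tested.

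Chance as the source of the counts was tested with other splits of the samples. With 24 libraries, only the real grouping and splits that exchange whole groups keep each library 3 beside libraries 1 and 2 of its group, which raises the count if library 3 is a mix, so these splits exclude nothing. Of 100 splits, 4 gave as many genes for treatment in old mice, the real one included, and 2 each for treatment in young mice and for the sex difference in old mice. For age by treatment, treatment over all mice, age, sex by treatment and sex it was 1 each. Real values and highest others were 1126 and 1825, 18 and 26, 1825 and 2307, 749 and 380, 179 and 114, 3231 and 958, 559 and 299, and 1314 and 353, in this order. The split with 1825 genes exchanged the treatment labels in 1 sex. Within each age and sex 10 splits are too few for a share under 0.05, with real values and highest others of 3175 and 420 in old males, 122 and 10 in old females, 24 and 0 in young males, and 25 and 10 in young females.

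With 16 libraries, chance was not excluded for age by treatment (5 of 100 splits; real value 2 and highest other 3), treatment over all mice (36; 1 and 2) or sex by treatment (37; 1 and 12). The splits, 18 or 3, were too few for a share under 0.05 elsewhere. Real values and highest others there were 6 and 2 for treatment in old mice, 1 and 1 in young mice, 438 and 5 for age, 136 and 1 for sex, 1 and 6 for the sex difference in old mice, 99 and 0 in old males, 1 and 0 in old females, 0 and 0 in young males, and 1 and 0 in young females.

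For lists called with 24 libraries, chance was not excluded for treatment in old mice (8 of 100 splits; 15 and 18), in young mice (18; 9 and 12), for age by treatment (5; 16 and 19) or for treatment over all mice (35; 10 and 17). For age, 3 of 100 splits called as many (17 and 18), which excludes nothing for the reason above. The median over the other splits of 24 libraries was 10 lists for treatment in old mice and 5 in young mice. It was 9 for age by treatment, 8 over all mice and 10 for age. With 16 libraries chance was not excluded for age by treatment (14 of 100; 13 and 17) or treatment over all mice (42; 10 and 17). Splits were too few for treatment in old mice (14 and 13), in young mice (6 and 10) and for age (19 and 17).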
